A study of Mus musculus with 11 samples.

How the data were processed

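The series holds 11 hybridisations of a custom Affymetrix glycan gene chip, 1 per sample, from 3 populations of CD4+ T cells sorted from mouse spleen: Treg (n = 3), CD25- CD45RBlow (n = 4) and CD25- CD45RBhigh (n = 4). The design text states 1127 probe sets for glycosylation and 119 reference probe sets, and the deposited table holds 1246. RNA was amplified and labelled with biotin. The labels name Trizol and the series text RNeasy for RNA extraction, which was not resolved.

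The deposited values are log2 expression per probe set, made by the authors with Robust Multichip Average (RMA), which corrects background, normalizes quantiles and summarises probes by median polish. Its version is not stated. The range of values, from 1.99 to 14.2, and the array medians are those of a log2 scale. No further normalization, filter or imputation was applied. The table names probe sets by RefSeq (984), UCSC (261) or other (1) identifiers. RefSeq identifiers gave gene symbols for 963 probe sets and 909 genes, and 283 probe sets had no name here. A mouse annotation was used for names only, so no coordinates are given. Where a gene had several probe sets, values are those of the brightest. Of the named probe sets 217 have an ID with the suffix s or x, so their signal may not be specific to 1 transcript. Among these are the probe sets of Klra9, Acvrl1, Ust, Igfbp4, St8sia1, Ugcg, Lgals1, Ccr6 and Ccr9. The reference probe sets are not marked in the table and were not used for scaling.

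Groups, comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data. A linear model with 1 mean per population was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 2.87, residual 8), for the comparisons Treg against CD45RBhigh, Treg against CD45RBlow, and CD45RBlow against CD45RBhigh. Tests were two-sided, with Benjamini-Hochberg adjustment over 1246 probe sets in each comparison and a threshold of 0.05, and intervals are at 95%. Genes named were, per comparison and direction, the 10 probe sets with the largest change among those past the threshold whose groups did not overlap, up to 4 members per list by smallest adjusted p, and genes that check the sort, of which Il2ra, Cd44 and Ccr7 are given. Genes named beyond this rule are said to be so.

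Of 21 gene lists with 453 gene names, 315 of them measured, the 18 with at least 5 measured genes were tested with camera from limma against the 909 named genes, at a preset correlation of 0.01. This made 54 tests, adjusted together. They were repeated with an estimated correlation and with fry, which tests whether a list moves on balance in a direction. Of the 8 calls made by camera, 0 held with an estimated correlation, and fry made 22 calls. Overlaps were compared with 100 simulations of unchanged groups that share arrays as the real ones do, and with overlaps after splitting the shared control arrays.

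Replicate numbers were tested for pairing by the correlation of deviations from the population mean, which had a median of 0.46 between arrays of 1 number (highest 0.56) and of 0.28 between arrays of other numbers within the same replicate set (highest 0.58). Part of the former therefore goes with the replicate set. The sample titles of 1 number also end in the same digits in each population, but no label says what these mark. A fit with the number as a block is given beside the counts. Alternatives were a random block, only the arrays compared, 3 other scalings, filters on dim probe sets, other moderation, 1 probe set per gene, a fold threshold and leaving out each array in turn. Fits by replicate set, and without probe sets with equal values within a population, were chosen after seeing the data. Simulated data had independent noise on each array, without any replicate structure, and 200 probe sets changed in Treg arrays in each of 20 runs. There the Treg against CD45RBhigh fit recovered 84.2% of changes of 0.5 on the log2 scale and 97.6% of changes of 1. False calls were 4.11% of calls. These rates need not hold for the real arrays, which have a replicate structure. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with pandas 2.3.3.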

Results

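Transcript levels of genes for glycosylation and of heavily glycosylated proteins were measured in 3 populations of CD4+ T cells sorted by flow cytometry from the spleens of C57BL/6 mice. The populations were CD25+ CD45RBlow cells, which the labels call regulatory T cells (Treg, n = 3, replicates 1, 2 and 4), CD25- CD45RBlow cells (n = 4) and CD25- CD45RBhigh cells (n = 4). CD25 is the alpha chain of the interleukin-2 receptor, and CD45RB is an isoform of a surface phosphatase that is high on naive CD4+ cells. Each of the 11 samples was hybridised to 1 array of a custom glycan gene chip, and values are on a log2 scale. Array medians lay between 4.85 and 4.94, and the number of arrays limits the precision of every value. The labels give an age of 4 to 6 weeks for the CD25- samples and no age for the Treg samples. A difference in age is therefore not excluded in the comparisons with Treg cells. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples. The series text speaks of freshly isolated and activated cells, but the labels name only the 3 sorted populations, so no activation was compared.

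The first principal component, with 56.5% of the variance, ran from Treg to CD45RBhigh arrays, and the second, with 24.8%, set the CD25- CD45RBlow arrays apart from both. Arrays of 1 population correlated at 0.991 to 0.998 across probe sets, and arrays of different populations at 0.956 to 0.984. Probe sets are not independent replicates, so these correlations describe the arrays only. Within populations, replicates 1 and 2 lay apart from replicates 3 and 4, and 257 probe sets differed between these replicate sets with the population in the model. Values within each replicate set are therefore given beside the main counts. A population mean under 3.64, the first quartile of all values, is read here as near background, and the size of a change against it as a lower bound. Genes with such a mean include Cxcl2, Gcnt1, Il21, Gcnt2, Dll1, St6galnac1, Il2 and Il12rb2. This cut may be too low for some probe sets. The myeloid markers Csf1r and Siglec1 read 5.02 to 5.07 and 4.69 to 4.79 in these sorted populations. Changes against means only somewhat above the cut, such as those of Klrd1, Il2ra and Il4, may therefore be lower bounds too.

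**Figure D1:**
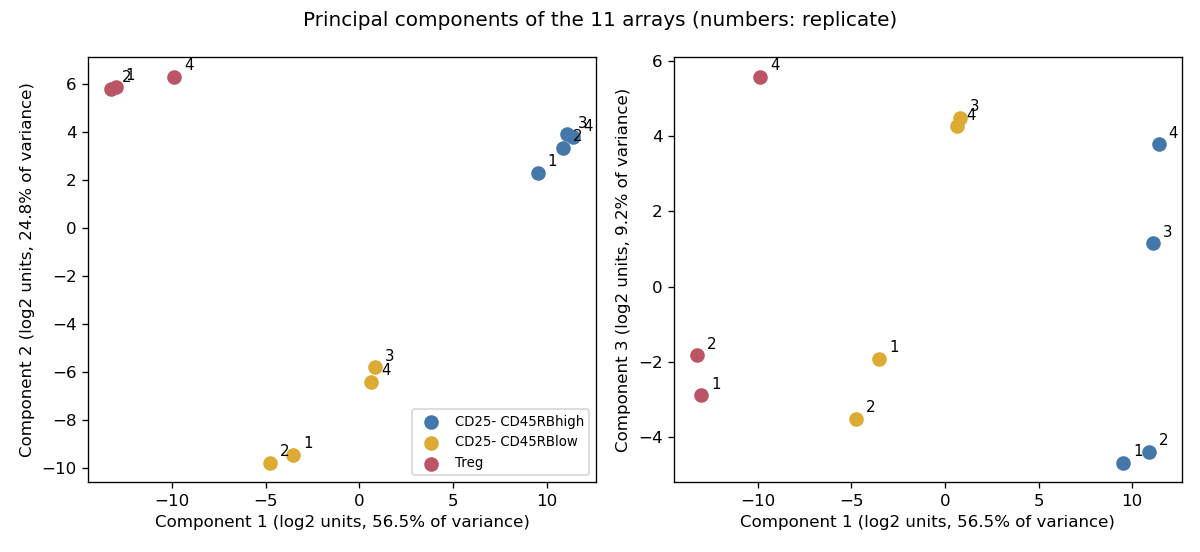
Principal components 1, 2 and 3 of the 11 arrays in log2 units, with colour for the population and numbers for the replicate. The 3 populations separate on components 1 and 2, which hold 56.5% and 24.8% of the variance, and component 3 with 9.24% parts replicates 1 and 2 from replicates 3 and 4 in each population.

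The comparison of Treg with CD25- CD45RBhigh cells asked which glycosylation genes differ between regulatory and naive-type CD4+ cells. Il2ra, which encodes CD25 and so checks the sort, was the gene that rose most in Treg cells, from 4.07 ± 0.27 (SD, n = 4) to 9.84 ± 0.17 (SD, n = 3), a 54.6-fold difference. Cd83, a surface glycoprotein of activated lymphocytes, was 53.1-fold higher. Klrg1, an inhibitory lectin-like receptor, was 30.5-fold higher, and Itgae, the integrin chain that binds E-cadherin, 22.1-fold higher. In the other direction Klrd1, a lectin-like receptor chain best known from natural killer cells, was 39.0-fold lower in Treg cells, at 3.93 ± 0.47 (SD, n = 3) against 9.22 ± 0.21 (SD, n = 4). Treg replicate 2 read 3.40, under the cut for near background, so this size may be a lower bound.

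In all, 235 of the probe sets (18.9%) passed an adjusted p of 0.05 in limma, 128 higher and 107 lower in Treg cells, and 80 of them differed at least 2-fold. With the replicate number as a block 330 passed, and the larger part was then lower, with 151 higher and 179 lower. At an unadjusted p under 0.05 there were 374. The 2 groups did not overlap at 311 probe sets (25%), where chance gives 5.71%. Further genes that rose were Il1rl1, an interleukin receptor chain (log2 fold change 4.16, SE 0.26), Sdc4, a heparan sulfate proteoglycan of the cell surface (3.74, SE 0.18), and Il10, an immunosuppressive cytokine (3.61, SE 0.26). Il2rb, the beta chain of the interleukin-2 receptor, rose by 3.51 (SE 0.21), the chemokine Cxcl2 by at least 3.34 (SE 0.31) and the chemokine receptor Ccr6 by 3.31 (SE 0.26). Genes that fell were Tgfbr3, a TGF-beta co-receptor that carries glycosaminoglycan chains (log2 fold change -2.99, SE 0.10), Igfbp4, which binds insulin-like growth factors (-2.75, SE 0.17), and Ust, a sulfotransferase of chondroitin and dermatan sulfate (-2.74, SE 0.14). The sialyltransferase St3gal6 (-2.64, SE 0.13), the TGF-beta family receptor Acvrl1 (-2.14, SE 0.13) and the lectin-like receptor Klra9 (-2.03, SE 0.22) fell as well. The adjusted p of these genes ran from 8.22e-09 for Il2ra to 3.94e-05 for Klra9. In each case every Treg array lay on 1 side of every CD45RBhigh array, which the rule for named genes requires.

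Among the glycosylation lists, O-GalNAc glycan synthesis (25 genes measured) had 1 gene that rose and 7 that fell in Treg cells, with the same counts adjusted over the list alone. Galnt10, Galnt6 and Galnt9, which start mucin-type O-glycans, fell by 1.15, 0.94 and 0.62 on the log2 scale, and Gcnt1, which branches them, rose by at least 1.35 (SE 0.23). The list as a set had an adjusted p of 0.0834 (camera), of 0.0315 with the replicate number as a block, and of 0.239 with an estimated correlation and no block. Of 19 sialyltransferases 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.772). St8sia1, which makes the ganglioside GD3, fell by 1.89 (SE 0.13), while St3gal2 rose by 1.15 (SE 0.14) and St3gal5, which makes the ganglioside GM3, by 0.80 (SE 0.07). Of 17 genes for fucosylation and selectin ligands 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.629). Among them were Fut7, which completes selectin ligands (0.95, SE 0.09), and the sulfotransferase Chst2 (2.26, SE 0.30). At an unadjusted p under 0.05, 4 of that list rose and 1 fell.

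Of 21 galactosyltransferase and poly-LacNAc genes 3 rose and 3 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.843). B4galt4 rose by 1.22 (SE 0.13) and Ggta1, which adds alpha-galactose, by 1.36 (SE 0.17). Of 43 genes for proteoglycan and glycosaminoglycan synthesis 3 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.474). Besides Ust, Xylt2, which starts glycosaminoglycan chains, fell by 1.19 (SE 0.16), and the chondroitin sulfotransferase Chst11 rose by 0.77 (SE 0.12). Of 14 glycosphingolipid genes St3gal5 rose while St8sia1 and Ugcg fell, or 2 rose and 4 fell with the replicate block, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.613). Ugcg, the glucosyltransferase that starts glycosphingolipids, fell by 1.13 (SE 0.09). Glycan degradation (27 genes) had 5 that rose and 8 that fell, or 5 and 9 adjusted over the list alone (camera adjusted p = 0.578). Arsb, a lysosomal sulfatase, fell by 1.15 (SE 0.12), whereas the sialidase Neu3 rose by 0.97 (SE 0.12).

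Of 38 genes for nucleotide sugars and their transport 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.912). The transporter Slc35d1 rose by 1.12 (SE 0.23) and Gmds, an enzyme of GDP-fucose synthesis, by 0.49 (SE 0.08). Slc35a5 fell by 0.76 (SE 0.12) and Cmas, which activates sialic acid, by 0.41 (SE 0.08). In N-glycan precursor synthesis and trimming (19 genes) 0 rose and 2 fell, or 0 and 6 with the replicate block, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.772), and in branching (11 genes) 0 rose and Man2a2, a Golgi mannosidase, fell by 1.08 (SE 0.20). The branching list had 1 that rose and 2 that fell adjusted over the list alone (camera adjusted p = 0.843). At an unadjusted p under 0.05 the precursor list had 1 up and 4 down and the branching list 1 up and 2 down. Of 8 galectins 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.629), with Lgals1 up by 1.48 (SE 0.12) and Lgals3 by 1.04 (SE 0.16). Of 13 Notch and Fringe genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.870), and the Notch ligand Dll1 rose by at least 0.59 (SE 0.09). With the replicate block the counts that rose and fell were 4 and 1 in fucosylation, 4 and 5 in galactosyltransferases, 6 and 5 in nucleotide sugars and 1 and 2 in branching. The mean, the median and the direction of the test did not share 1 sign for the sialyltransferases, fucosylation, nucleotide sugars, branching, galectins, Notch and naive T cell lists.

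**Figure D2:**
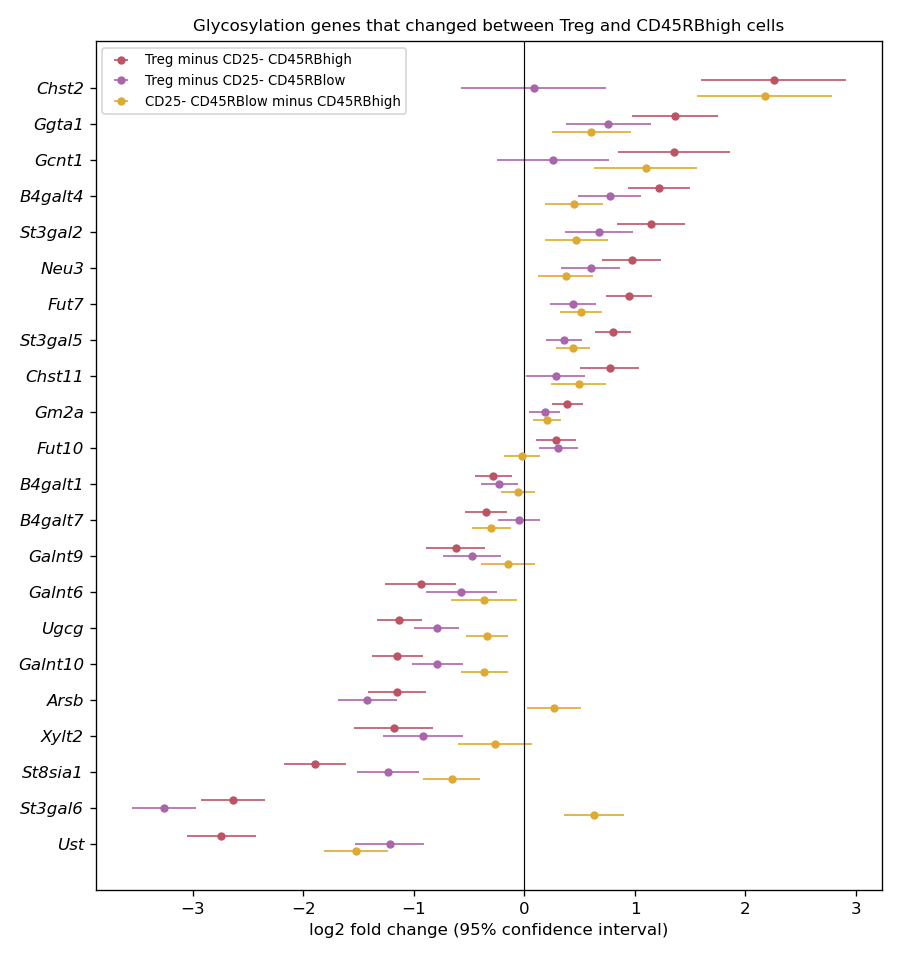
Log2 fold changes with 95% confidence intervals in the 3 comparisons for 22 of the glycosylation genes that passed the threshold between Treg and CD45RBhigh cells, ordered by that change. Ust and St3gal6 fell most in Treg cells (-2.74 and -2.64) and Chst2 rose most (2.26), and St3gal6 was higher in CD45RBlow than in CD45RBhigh cells (0.63).

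All 12 measured genes of the regulatory T cell signature rose in Treg cells, also adjusted over the list alone (camera adjusted p = 2.35e-19; adjusted p = 0.142 with an estimated correlation). Of 18 chemokine receptors 10 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.98e-05; adjusted p = 0.444 with an estimated correlation), and the receptors of no other list did not pass as a set (camera p = 0.222). Among them Ccr8 rose by 2.59 (SE 0.11), Ccr2 by 2.90 (SE 0.25) and Cxcr3 by 1.93 (SE 0.15). Of 21 markers of activated and memory T cells 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00162; adjusted p = 0.845 with an estimated correlation), and without the chemokine receptors the list no longer passed (camera p = 0.0604). Il12rb1, a chain of the interleukin-12 receptor, rose by 2.12 (SE 0.12). Of 6 naive T cell markers 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.464), with Il7r, the interleukin-7 receptor, down by -1.28 (SE 0.08) and Ccr7, which guides cells to lymph nodes, down by -1.01 (SE 0.10). The adhesion receptor Cd44 rose by 1.44 (SE 0.34, adjusted p = 0.0120), a call that ended without Treg replicate 1 (1.22, adjusted p = 0.0596). The 1 integrin measured, Itgae, is given above.

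Markers of other cell types moved with the populations as follows. Of 6 markers of natural killer and CD8 T cells Il2rb rose and 3 fell, Klrd1 among them, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.415). Klra3, also among those that fell, read near background in both populations (2.61 in Treg and 3.05 in CD45RBhigh cells). Of 4 B cell markers 2 rose, Cd72 (0.54) and Cd22 (0.29), and both calls ended without Treg replicate 1, at adjusted p = 0.0815 and 0.0734. Of 14 myeloid and dendritic cell markers 0 rose and 2 fell, and 0 adjusted over the list alone (camera adjusted p = 0.544), with 0 up and 4 down at an unadjusted p under 0.05. Of 3 platelet and erythroid markers Selp rose by 0.37 (SE 0.09), a call that ended without Treg replicate 4 (adjusted p = 0.0572).

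Within replicates 1 and 2 the comparison of Treg with CD45RBhigh cells gave 229 probe sets and within replicates 3 and 4, with 1 Treg array, 182. A separate fit of the arrays of replicates 3 and 4 alone gave 88.

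The comparison of Treg with CD25- CD45RBlow cells set 2 populations with low CD45RB against each other. Il2ra was 12.8-fold higher in Treg cells, at 9.84 ± 0.17 (SD, n = 3) against 6.17 ± 0.36 (SD, n = 4), and Sdc4 was 9.87-fold higher. Klrg1 was 7.40-fold, Cxcl2 at least 7.40-fold and Cd83 6.27-fold higher. Klrd1 was 20.4-fold lower, the chemokine receptor Cxcr6 10.2-fold lower and St3gal6 9.62-fold lower in Treg cells. The cytokine genes Il4 and Ifng, which encode interleukin-4 and interferon-gamma, were 6.30-fold and 5.72-fold lower.

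Of all probe sets 156 (12.5%) passed, 84 higher and 72 lower in Treg cells, and 54 differed at least 2-fold. With the replicate number as a block 245 passed, 112 higher and 133 lower. At an unadjusted p under 0.05 there were 281, and the groups did not overlap at 266 (21.3%, where chance gives 5.71%). Il10 (2.52, SE 0.26), Itgae (2.52, SE 0.28), Il1r2, a decoy receptor for interleukin-1 (2.10, SE 0.30), Cd74, the invariant chain of class II molecules (1.94, SE 0.13), and Il1rl1 (1.78, SE 0.26) also rose. Xcl1 and Ccl5, both chemokines, fell by 2.66 (SE 0.23) and 2.52 (SE 0.19), as did 2 probe sets with no gene name here, by 2.85 and at least 2.61. Il21, a cytokine of helper T cells, was lower by a log2 fold change of -2.27 (SE 0.61, adjusted p = 0.0304), a size that is a lower bound because its Treg mean was near background. Its call ended without CD45RBlow replicate 1 (adjusted p = 0.0886) and without Treg replicate 1 (0.0856), 2 (0.0803) or 4 (0.0937). For the other named genes the adjusted p ran from 8.16e-08 for St3gal6 to 0.000735 for Il1rl1. Their groups did not overlap, which the rule for named genes requires.

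In the O-GalNAc list 1 gene rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.374), with Galnt10 at -0.79 (SE 0.10) and Galnt14 at 0.30 (SE 0.06). Of the sialyltransferases 3 rose and 4 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.795). St8sia1 fell by 1.24 (SE 0.13), St3gal2 rose by 0.68 (SE 0.14) and St3gal5 by 0.36 (SE 0.07). In fucosylation and selectin ligands 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.629), with Fut7 up by 0.44 (SE 0.09). Of the galactosyltransferases 2 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.737). B4galt4 rose by 0.77 (SE 0.13) and Gcnt2, which branches poly-LacNAc, fell by at least 0.64 (SE 0.12). In glycosaminoglycan synthesis 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.599), with Ust down by -1.22 (SE 0.14) and Xylt2 by -0.92 (SE 0.16). In glycosphingolipid synthesis 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.492), and Ugcg fell by 0.79 (SE 0.09). In glycan degradation 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.629), with Arsb at -1.42 (SE 0.12) and Neu3 at 0.60 (SE 0.12). Of the nucleotide sugar genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.629), with Slc35d1 up by 1.44 (SE 0.23) and Gmds by 0.40 (SE 0.08).

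In N-glycan precursor synthesis, N-glycan branching and the galectins limma called 0 genes between Treg and CD45RBlow cells, also adjusted over each list alone (camera adjusted p = 0.924, 0.870 and 0.772). At an unadjusted p under 0.05 these lists had 3, 1 and 2 genes, and the blocked fit called 1 in each. Of the Notch genes Dll1 rose by at least 0.69 (SE 0.09) and 0 fell, also adjusted over the list alone (camera adjusted p = 0.668), with 2 up and 1 down at an unadjusted p under 0.05. With the replicate block the counts that rose and fell were 1 and 8 in O-GalNAc synthesis, 3 and 2 in galactosyltransferases, 1 and 5 in glycosaminoglycan and 1 and 4 in glycosphingolipid synthesis, 5 and 5 in degradation, 7 and 2 in nucleotide sugars and 2 and 1 in the Notch genes. The mean, the median and the direction of the test did not share 1 sign for O-GalNAc synthesis, sialyltransferases, galactosyltransferases, branching, glycosphingolipids, degradation, galectins and myeloid markers.

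Of the 12 signature genes 10 rose in Treg over CD45RBlow cells and 0 fell, or 11 adjusted over the list alone (camera adjusted p = 3.33e-11; adjusted p = 0.239 with an estimated correlation). Markers of activated and memory T cells went the other way, with 10 of 21 lower in Treg cells and 1 higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 7.82e-09; adjusted p = 0.431 with an estimated correlation). Cxcr6, Ccl5, Il4 and Ifng were among those that fell, and the chemokine Ccl1 rose by 1.18 (SE 0.11). Of the chemokine receptors 3 rose and 3 fell, or 3 and 7 with the replicate block, and 4 and 5 adjusted over the list alone (camera adjusted p = 0.475), with Ccr8 at 1.51 (SE 0.11) and Cxcr3 at -1.54 (SE 0.15). Of the naive markers 1 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.492), and Il7r fell by 0.77 (SE 0.08). Igf1r rose by 1.18 (SE 0.26), a call that ended without Treg replicate 1 (adjusted p = 0.0548). Cd44 differed by -0.06 (SE 0.34, adjusted p = 0.943) and Ccr7 by -0.32 (SE 0.10, adjusted p = 0.0756).

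Of the natural killer and CD8 markers Klrd1 fell and Il2rb rose by 0.95 (SE 0.21), a call that ended without Treg replicate 1 (adjusted p = 0.0528), and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.163). Of the B cell markers Cd72 rose by 0.85 (SE 0.14), and Cd22 had a log2 fold change of -0.30 (adjusted p = 0.0235), a call that ended without CD45RBlow replicate 2 (0.0579) or 3 (0.0580) or Treg replicate 1 (0.0514), 2 (0.0892) or 4 (0.0614). Of the platelet and erythroid markers Selp rose by 0.48 (SE 0.09), and of the myeloid markers 0 rose or fell in limma, also adjusted over the list alone (camera adjusted p = 0.889), with 1 at an unadjusted p under 0.05 and 1 in the blocked fit. Within replicates 1 and 2 there were 172 probe sets and within replicates 3 and 4, with 1 Treg array, there were 129. A separate fit of replicates 3 and 4 alone gave 49.

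The comparison of CD25- CD45RBlow with CD25- CD45RBhigh cells asked how the CD25- cells differ with the level of CD45RB. In the CD45RBlow cells the chemokine receptors Cxcr6, Cxcr3 and Ccr2 were 13.6-fold, 11.1-fold and 10.2-fold higher. Cxcr6 read 11.19 ± 0.18 (SD, n = 4) against 7.43 ± 0.33 (SD, n = 4). Ifng was 9.10-fold and Cd83 8.48-fold higher, and Il2ra, although these cells were sorted as CD25-, was 4.28-fold higher at 6.17 ± 0.36 (SD, n = 4) against 4.07 ± 0.27 (SD, n = 4). Falls were smaller, with Ust 2.88-fold, Igfbp4 2.12-fold and the sialyltransferase St8sia6 2.08-fold lower.

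Of all probe sets 157 (12.6%) passed, 95 higher (60.5%) and 62 lower in CD45RBlow cells, and 54 differed at least 2-fold, 48 of them higher. The split between higher and lower depended on the scaling, with 98 higher and 129 lower after quantile normalization and 112 higher and 32 lower after cyclic loess. With the replicate number as a block 271 passed, 125 higher and 146 lower. At an unadjusted p under 0.05 there were 354, and the groups did not overlap at 222 (17.8%, where chance gives 2.86%). Ccr9, a receptor for homing to the gut, rose by 2.68 (SE 0.30), Il2rb by 2.57 (SE 0.19) and Il4 by 2.54 (SE 0.22). Il21 rose by at least 2.62 (SE 0.56, adjusted p = 0.00974), with a spread in CD45RBlow cells of 1.48 (SD, n = 4). Its change was 3.77 in replicates 1 and 2 and 1.47 in replicates 3 and 4, and the difference between the sets passed (limma adjusted p = 0.0278). Klrd1 fell by 0.94 (SE 0.19). Ovgp1, an oviduct glycoprotein gene, had a log2 fold change of -0.90 (SE 0.25, adjusted p = 0.0394). Its call ended without 8 of the 11 arrays in turn, which were CD45RBhigh replicates 1 to 4, CD45RBlow replicates 1 to 3 and Treg replicate 1, at adjusted p from 0.0510 to 0.110.

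Of 25 O-GalNAc genes 1 rose and 2 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.415), with Gcnt1 up by at least 1.10 (SE 0.21). Of the sialyltransferases 5 rose and 2 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.415). St6galnac1 rose by at least 0.83 (SE 0.16) and St3gal5 by 0.44 (SE 0.07), and St8sia6 and St8sia1 fell by 1.05 (SE 0.14) and 0.66 (SE 0.12). In fucosylation and selectin ligands 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.870), with Chst2 at 2.17 (SE 0.28) and Fut7 at 0.51 (SE 0.09), and 3 up and 2 down at an unadjusted p under 0.05. Of the galactosyltransferases 4 rose and 1 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.492), with Gcnt2 up by at least 0.77 (SE 0.11) and B3galt5 by 0.27 (SE 0.06). In glycosaminoglycan synthesis 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.613), but 3 rose and 1 fell after cyclic loess. Chsy1, a chondroitin synthase, rose by 1.78 (SE 0.26) and Chst11 by 0.49 (SE 0.11). In glycosphingolipid synthesis 1 rose and 2 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.889). Of these, Ugcg at -0.34 lost its call without CD45RBhigh replicate 1 (adjusted p = 0.0753), CD45RBlow replicate 1 (0.0720) or CD45RBlow replicate 2 (0.0743). In glycan degradation 2 rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.889), with 5 up and 6 down at an unadjusted p under 0.05 and 4 up and 6 down with the replicate block.

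Of the nucleotide sugar genes 0 rose and Slc35a5 fell by 0.58 (SE 0.11), also adjusted over the list alone (camera adjusted p = 0.629), with 2 up and 5 down at an unadjusted p under 0.05 and 0 up and 6 down with the replicate block. In N-glycan precursor synthesis 0 rose and 1 fell, and 0 adjusted over the list alone (camera adjusted p = 0.629), with 0 up and 2 down at an unadjusted p under 0.05 and 0 up and 5 down with the replicate block. In branching limma called 0, also adjusted over the list alone (camera adjusted p = 0.795), with 2 up and 2 down at an unadjusted p under 0.05 and 2 in the blocked fit. Of the galectins Lgals3 rose by 1.27 (SE 0.14) and Lgals1 by 1.19 (SE 0.11) and 0 fell, also adjusted over the list alone (camera adjusted p = 0.415), with the same 2 and 0 at an unadjusted p under 0.05. Of the Notch genes 0 rose and 1 fell, and 0 adjusted over the list alone (camera adjusted p = 0.795), with 1 up and 1 down at an unadjusted p under 0.05. With the replicate block the counts that rose and fell were 1 and 5 in O-GalNAc synthesis, 6 and 4 in galactosyltransferases, 2 and 7 in glycosaminoglycan and 2 and 3 in glycosphingolipid synthesis, 2 and 1 in the galectins and 1 and 1 in the Notch genes. The mean, the median and the direction of the test did not share 1 sign for the sialyltransferases, fucosylation, galactosyltransferases, branching, galectins, naive and natural killer lists.

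Of 21 markers of activated and memory T cells 16 rose in CD45RBlow cells and 0 fell, also adjusted over the list alone (camera adjusted p = 7.70e-21; adjusted p = 0.142 with an estimated correlation). Besides the receptors above, Il12rb1 rose by 2.05 (SE 0.11) and Cd44 was 2.84-fold higher. All 12 signature genes of regulatory T cells rose here too, also adjusted over the list alone (camera adjusted p = 3.84e-18; adjusted p = 0.142 with an estimated correlation), with Lgals1, Il2rb, Il2ra and Cd83 of smallest adjusted p. Of the chemokine receptors 11 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.33e-09; adjusted p = 0.239 with an estimated correlation), with Cxcr5 up by 2.10 (SE 0.20), and the receptors of no other list did not pass as a set (camera p = 0.156). Of the naive markers 4 of 6 fell, among them Il6ra by 0.72 (SE 0.10), Ccr7 by 0.69 (SE 0.10) and Il7r by 0.50 (SE 0.07), while Ccr9 rose, or 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.479). Of the natural killer and CD8 markers Il2rb rose and Klrd1 fell, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.889). The B cell marker Cd22 rose by 0.59 (SE 0.07), 3 myeloid markers fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.578), and of 3 platelet and erythroid markers 0 passed in limma, at an unadjusted p under 0.05 or in the blocked fit. The myeloid markers that fell were Siglech (-0.53), Clec10a (-0.31) and Cd209a (-0.26), and both means of Siglech (3.01 and 3.54) read near background.

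Within replicates 1 and 2 there were 181 probe sets and within replicates 3 and 4 there were 132. The change was larger in replicates 1 and 2 at 116 of the 157, with a median size of 0.82 against 0.58 on the log2 scale, and a fit of replicates 3 and 4 alone gave 63.

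**Figure D3:**
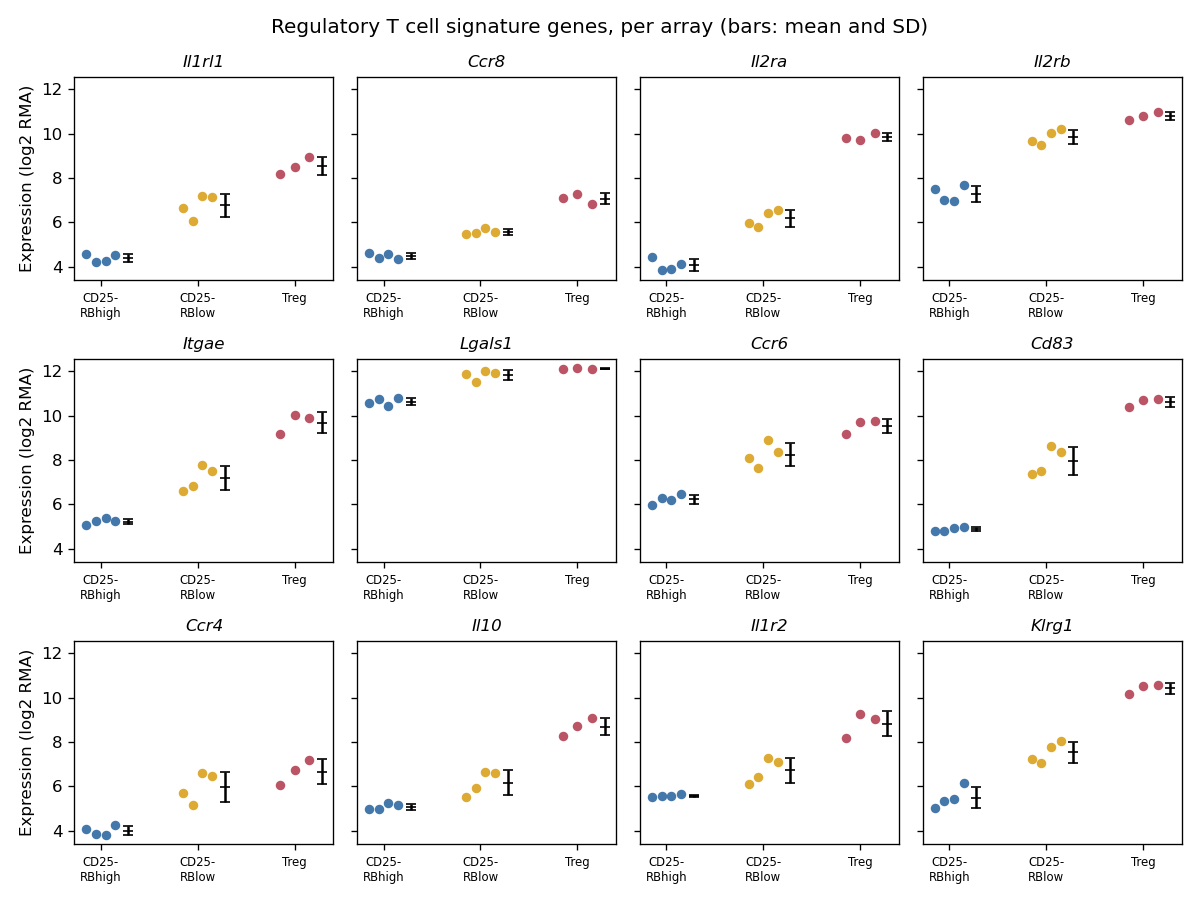
Log2 expression of the 12 measured signature genes of regulatory T cells on each array, with points for arrays and bars for the mean and SD of each population (n = 4, 4 and 3). For Il2ra the means are 4.07 in CD45RBhigh, 6.17 in CD45RBlow and 9.84 in Treg cells, and CD45RBlow lies between the other populations for every gene.

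Treg and CD25- CD45RBlow cells shared part of their differences from CD45RBhigh cells. At 108 probe sets both populations changed in the same direction, 61 up and 47 down, and at 3 in opposite directions. Cd83, Il2ra, Il2rb, Ccr2, Cxcr3, Chst2, Gcnt1 and Lgals1 were higher in both, and Ust, Igfbp4, St8sia1, Il7r and Ccr7 lower. Unchanged simulated groups against the same control arrays shared a median of 0 and at most 0 probe sets, and independent lists of these sizes share 15.1. Groups without changes give almost no calls, so the simulated count cannot show what shared arrays add between populations that differ. With the 4 control arrays split 2 and 2 the overlap was 46 to 60. The covariance of the log2 fold changes was 0.205 against 0.00750 simulated, and 0.191 to 0.202 with split controls, and their correlation across probe sets was 0.66 against 0.47 simulated. With the replicate block 173 probe sets were shared, 79 up and 94 down, and the share that was higher moved with the scaling, to 62 of 134 after quantile normalization and 73 of 100 after cyclic loess. Replicates 3 and 4 alone gave 36.

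At 107 probe sets Treg cells differed from both CD25- populations in the same direction, 68 higher and 39 lower, and at 6 in opposite directions. Sdc4, Cxcl2, Fut7, B4galt4, St3gal2, St3gal5, Neu3, Dll1, Gmds and Slc35d1 were higher in Treg cells than in both, and Klrd1, St3gal6, St8sia1, Ugcg, Arsb, Galnt10, Xylt2, Ust and Il7r lower. Simulated unchanged groups gave a median of 0 and at most 1, a count with the same limit as above, and independent lists share 14.8. The covariance was 0.218 against 0.00973 simulated, and the correlation across probe sets 0.68 against 0.57. The 3 Treg arrays cannot be split with at least 2 on each side, so part of this excess may come from the shared arrays. With the replicate block there were 171, 84 higher and 87 lower, so that the larger part was then lower, and in replicates 3 and 4 alone 36.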

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

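The tests of Klrd1, of the signature genes and of the CD45RBlow sort were chosen after the result was seen, whereas those of other splits of the arrays and of a batch common to all populations were written before.

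Klrd1 was lower in Treg cells than in both CD25- populations, by -5.29 against CD45RBhigh and -4.35 against CD45RBlow cells. Scaling between arrays is argued against, since under 3 other scalings the smallest fall was -4.34. Natural killer or CD8 T cells in the CD25- sorts, which the CD4 gate would remove, stay open. Il2rb, also in the list of natural killer and CD8 markers, rose by 3.51 in Treg over CD45RBhigh cells and was left out of the test. The other 4 receptors of that list (Klra3, Klra8, Klra7 and Klrk1) had a median of -0.42 between Treg and CD45RBhigh cells. Only 2 of them read above the first quartile of 3.64 in CD45RBhigh cells, too few for the test. Klra9, a related receptor outside the list, read 6.75 in CD45RBhigh cells and had a change of -2.03. Its probe set has the suffix s, so this signal may not be specific to Klra9. Klrc1 and Klrb1f, also outside the list, were higher in CD45RBlow than in Treg cells, as was Klrd1. They were also higher in CD45RBlow than in CD45RBhigh cells, where Klrd1 was lower. A difference between the sorted populations in their own expression also stays open and was not tested.

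All 12 measured signature genes of regulatory T cells read between the CD45RBhigh and Treg levels in CD25- CD45RBlow cells. Scaling is argued against, since all 12 stayed higher than in CD45RBhigh cells past the threshold under 3 other scalings. Cells with the profile of the Treg arrays, mixed into the CD45RBlow sort in 1 share, would give the same share on the linear scale for the genes other than Il2ra, whose level the sort on CD25 sets. Il10 gave 10.1%, with an upper bound of 17.7%, and Lgals1 72.0% (53.5 to 96.8). Of 11 intervals 4 lay above that bound (10000 resamples), which argues against such a mixture as the whole cause. The bound is that of the gene with the lowest share of the 11, picked from these data. The argument also takes array signal as proportional to RNA for each gene, which was not tested. Treg cells with low CD25, whose profile was not measured, and expression by the CD45RBlow cells themselves stay open.

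Replicates 1 and 2 lay apart from replicates 3 and 4 at 257 probe sets, 139 higher and 118 lower in the latter. Among the genes with the smallest adjusted p were Lfng (1.17 higher in replicates 3 and 4), Ncstn (0.80) and Galnt1 (-0.63), named after their values were seen. Of 71 probe sets chosen in CD45RBhigh cells, 95.8% had the same sign in CD45RBlow and 97.2% in Treg cells, which is consistent with a batch that shifts all populations alike. A CD45RBlow sort further from CD45RBhigh cells in replicates 1 and 2 may add to it and stays open, with a slope of 0.25 against -0.09 and -0.06 for the other ways to halve the replicates. The labels name no batch, and no biological explanation was tested.

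In the CD25- populations the highest or lowest array was compared with the others, relative to the range of its population. It lay apart in 16 of 282 combinations of gene and population, and chance gives about 5%. Treg arrays were not checked in this way. Among CD45RBhigh arrays, St3gal6 read 7.18 in replicate 4 against 7.59 to 7.63 in the others. Ovgp1 read 8.43 in replicate 4 against 7.64 to 7.76. An unnamed probe set read 7.07 in replicate 1 against 6.09 to 6.22. B4galt4 read 4.06 in replicate 3 against 4.31 to 4.35, and B4galt1 10.8 in replicate 4 against 10.5. Lgals12 read 3.86 in replicate 1 against 3.78 to 3.79. Mgat5 read 5.15 in replicate 4 against 5.31 to 5.33, and Mgat3 4.22 in replicate 2 against 4.06 to 4.08. Jag2 read 6.28 in replicate 4 against 5.55 to 5.64, and Dll4 5.52 in replicate 1 against 5.37 to 5.40. Gcnt1 read 2.33 in replicate 2 against 2.92 to 2.95. Among CD45RBlow arrays, Fut7 read 6.44 in replicate 4 against an equal value of 6.42 in all 3 others, so this small gap is the whole range. Mgat4a read 4.47 in replicate 3 against 4.83 to 4.85. Klra8 read 3.76 in replicate 2 against 4.01 to 4.03, and Notch2 9.57 in replicate 2 against 8.68 to 8.78. Ppbp read 3.50 in replicate 4 against 3.35 to 3.37.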

How the results depend on the processing

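The fits by replicate set, by replicates 1 and 2 or 3 and 4 only, and without probe sets with equal values within a population were chosen after seeing the data. Counts are given for Treg against CD45RBhigh, Treg against CD45RBlow, CD45RBlow against CD45RBhigh, the overlap and the Treg-specific probe sets, which were 235, 156, 157, 108 and 107. With the replicate number as a block, Treg against CD45RBlow moved to 245, CD45RBlow against CD45RBhigh to 271, the overlap to 173 and the Treg-specific probe sets to 171. With the replicate set as a factor, the comparisons with CD45RBlow cells moved to 238 for Treg and 247 for CD45RBhigh cells. With the probe sets below the median brightness left out, Treg against CD45RBlow gave 103 of 623 tested. At a log2 fold change of at least 1 all 5 counts were 80, 54, 54, 36 and 37, fewer by construction. Replicates 3 and 4 only, with 5 arrays and a lone Treg array assumed to vary like the other groups, gave 88, 49, 63, 36 and 36. Camera made 8 list calls, 0 with an estimated correlation, and fry 22. Where not given, the cause was not tested. Leaving out each array in turn gave 164 to 227, 110 to 162, 113 to 151, 76 to 94 and 80 to 107, and 8 to 9 list calls. The other counts stayed within 1.5 times the value reported, and 0 of 253 values of named genes and comparisons reversed past the threshold. Of these, 83 lost their call in replicates 3 and 4 only and 34 without Treg replicate 1. Scaling on the reference probe sets was not run, since nothing marks them. No control probe sets were in the table to leave out. Equal values on at least 2 arrays of 1 population occurred at 439 probe sets, 346 of them below the median brightness, with a median residual SD of 0.0942 against 0.149 elsewhere, which limits what the spread shows near background. Without them 195 of 196, 124 of 125 and 124 of 133 calls were kept.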

Other observations

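The tests of other splits of the arrays were written before the result was seen, whereas the genes named in the next 2 paragraphs were chosen after their values were seen, without a test of enrichment. Of these, Tgfbr3 and Acvrl1 are also named by the rule for Treg against CD45RBhigh cells and kept that call without each array in turn, and the other genes were not refitted in this way.

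CD25- CD45RBlow cells stood above both other populations at 31 probe sets. Il2, which encodes interleukin-2 and reads near background in CD45RBhigh cells, was higher by at least 2.41 (SE 0.22) than in CD45RBhigh cells, and its log2 fold change between Treg and CD45RBlow cells was -2.09 (SE 0.24). For Csf2, which encodes a myeloid growth factor, the values were 0.97 (SE 0.14) and -0.89 (SE 0.15). For Il12rb2 they were 0.94 (SE 0.14) and -1.26 (SE 0.16), the size of the latter a lower bound because its Treg mean was near background. For Il18rap, a chain of the interleukin-18 receptor, they were 1.35 (SE 0.11) and -1.07 (SE 0.12).

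In Treg cells Tgfbr1, which encodes a TGF-beta receptor, was higher by 1.40 (SE 0.15) than in CD45RBhigh and by 1.28 (SE 0.15) than in CD45RBlow cells. Tgfbr2, which encodes its partner receptor, had log2 fold changes of -0.89 (SE 0.06) and -0.71 (SE 0.06). Tgfbr3 had log2 fold changes of -2.99 (SE 0.10) and -2.27 (SE 0.10), and Acvrl1 -2.14 (SE 0.13) and -1.45 (SE 0.13). Bmpr2 had 0.52 (SE 0.08) and 0.42 (SE 0.08). Il10rb, a chain of the interleukin-10 receptor, was higher by 0.86 (SE 0.09) and 0.73 (SE 0.09), and Prdm1, a transcriptional repressor, by 1.58 (SE 0.10) and 0.77 (SE 0.10). Cmah, which hydroxylates sialic acid, had -1.37 (SE 0.14) and -0.71 (SE 0.14).

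Other splits of the arrays compared were fitted in the same way. For Treg against CD45RBhigh cells 1 of 35 splits, the real one, gave as many probe sets (210, highest other 18). For Treg against CD45RBlow cells it was again 1 of 35 (138, highest other 49). For CD45RBlow against CD45RBhigh cells it was also 1 of 35 (142, highest other 42). This is the smallest share that 35 splits can give, so chance is unlikely for each but not excluded. The highest others follow the replicate set, and the 7 other splits that part as many replicate numbers gave at most 0, 1 and 0. Of 100 regroupings of all arrays, 1, the real one, gave as large an overlap (108, highest other 0). Again only the real one gave as many Treg-specific probe sets (107, highest other 72). Regrouping mixes the populations and so removes most differences that could be shared. These counts therefore speak only against groups that do not differ at all. They cannot show whether populations that differ share more than chance would give. For the number of gene list calls 15 of 100 regroupings gave as many as the real 8, and the highest other was 10, so chance is not excluded for that number.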
